A study of Mus musculus with 30 samples.

How the data were processed

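Blood was drawn by cardiac puncture from male C57BL/6J mice of the genotypes p38WT, p38DKI and p38DN, either 24 h after 7 Gy or at dose 0, per the labels. There were 5 mice per genotype and treatment, giving 6 groups and 30 one-colour arrays. DKI and DN are used as the labels write them. Per the file headers the arrays were read with Agilent Feature Extraction 12.0.2. The version of the software behind the deposited value table was not given in the sources used here.

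The authors' scanner files give a processed signal in intensity units for each of 44397 spots, of which 43020 were not controls and stood for 39429 distinct probes. A set of 399 probes was spotted 10 times each. The deposited value table holds log2 values for 18417 probes, 18391 of them on the scanner files, with 21825 empty cells. For probes spotted once it equalled the log2 processed signal minus 1 constant per array (between -0.64 and 1.16). It differed by over 0.01 for 239 probes, all 239 of them spotted several times. Because the table lacks many probes, the fits used the processed intensity from the scanner files, and the deposited log2 values served as an alternative.

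Processed intensity was taken to log2, spots that the scanner software marked as non-uniform or as population outliers were left out, and repeated spots of a probe were averaged. The 75th percentile of each array was subtracted, so all levels below are log2 relative to that percentile. That percentile lay between intensities of 43.7 and 244.2. Between 39.72 and 63.24% of the probes of an array were well above background. A probe was kept when it was well above background on at least 4 of the 5 arrays of at least 1 group and had a value on at least 20 arrays, which left 23617 probes. Probes were named through the RefSeq accession (29056), the symbol (3150) or a synonym (116), and 7107 kept the name of the array file. The brightest kept probe stood for a gene, giving 18726 genes or unnamed features, 15141 of them with a name in the reference table. Probe positions are those of the mouse build mm9.

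Group means were fitted with limma 3.58.1 (24 residual degrees of freedom, moderated variances), and 10 comparisons were taken from the single fit. Genes passed at a Benjamini-Hochberg adjusted p under 0.05 over all 18726 genes. The mouse was the unit of replication. Fixed lists of genes (23 lists, 735 entries, 681 measured) were written from general knowledge and tested with camera at a preset correlation of 0.01, with p adjusted over the 23 lists. The same test with a correlation estimated from the data is given beside each list that it no longer called, and fry was run as a further alternative. Comparisons, lists, thresholds and most alternatives were chosen before the data were examined.

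Genes were named by a fixed rule. For each irradiation effect these were the 10 largest rises and the 10 largest falls among genes past the threshold, well above background on all 5 arrays of the brighter group and without overlap between the 5 and 5 arrays. Other comparisons named up to 5 of each, and a difference between irradiation effects needed no overlap in at least 1 of its genotypes. The 3 members with the smallest p of each list and the genes Mapk14 and Mapk11 were added. A fold change is written as "at least" where no array of the dimmer group was well above background. For that bound each level in the dimmer group was raised to at least the lowest level of any well detected probe on its array.

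A simulation on the same layout changed 200 genes. Of 50 genes each, 2% were found at a log2 change of 0.5, 34% at 1, 74% at 2 and 96% at 4. Of 18234 unchanged genes 3 were called, and the only list called of 23 was the 1 that had been shifted. The simulated noise was independent between genes and held no slide or liver effect. It therefore cannot show how often lists of genes that move together are called falsely. Position tests drew 100000 random gene sets and counted genes within 10 Mb. Their permutation p treats genes as independent and does not allow for neighbouring genes that change together, so it may be too small. Normexp background correction, used as an alternative, added an offset of 50 to the signal, which shrinks log2 changes of dim probes. The analysis used R 4.3.3, data.table (version 1.17.8), jsonlite 2.0.0, Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9. The value of 1 gene is not reported here.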

Results

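RNA of mouse blood was measured on 30 one-colour arrays, 5 per group, in p38WT, p38DKI and p38DN mice either without irradiation or 24 h after exposure to 7 Gy. The series asks how signaling through p38, a stress-activated protein kinase, bears on gene expression used to read radiation exposure. Genes numbered 18726 after dim probes were left out, and the number of arrays limits the precision of every value. Levels are log2 relative to the 75th percentile of each array, given with the SD over n = 5 arrays. Fold changes carry the standard error (SE) of the log2 change, which comes from a spread pooled over all groups and not from the compared groups alone. The p38WT and p38DKI arrays filled slides 1 to 5 and were scanned on 1 day. The p38DN arrays filled slides 6 to 10 and were scanned in an earlier period, so for p38DN against p38WT batch and group cannot be told apart.

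Transcripts typical of liver were present on some arrays. The mean of 46 liver markers stood 9.88 (log2) above the median of the other arrays on p38DKI irradiated array 2. The excess was 7.80, 8.77 and 8.76 on p38DN unirradiated arrays 2, 4 and 5, and 4.28 on p38DKI unirradiated array 1. On p38DN irradiated arrays 2 and 4 it was 4.03 and 3.8. On the p38WT arrays the excess was at most 0.226. Heart muscle markers (19 tested) stood 4.49 above the median on p38WT irradiated array 2, 3.64 on p38DN irradiated array 3 and 3.18 on p38WT unirradiated array 1.

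**Figure D1:**
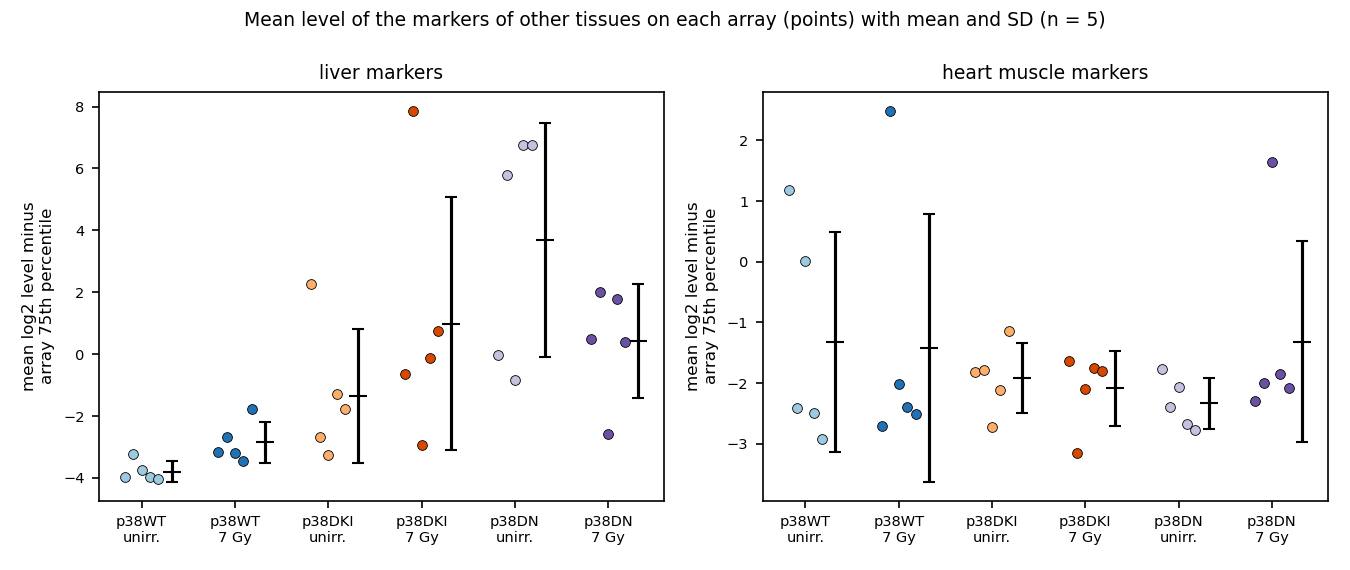
Mean level of liver and heart muscle markers (log2 relative to the 75th percentile) on each of the 30 arrays by group, 1 point per array. The liver markers reached 7.87 on p38DKI irradiated array 2 and 6.76 on p38DN unirradiated array 4, and the heart markers 2.49 on p38WT irradiated array 2.

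The first question was what irradiation did to blood transcripts of p38WT mice. B cell transcripts fell most. Vpreb3, a gene of the B lineage on chromosome 10 (mm9, 75412326 to 75412385), went from 4.84 ± 0.439 to -1.50 ± 0.971 (SD, n = 5), an 81.3-fold fall (log2 -6.35, SE 0.392, adjusted p = 1.18e-11). Slfn4, an interferon-inducible Schlafen gene on chromosome 11 (83002974 to 83003033), rose 59.3-fold (log2 5.89, SE 0.457, adjusted p = 6.57e-10), from -1.36 ± 1.01 to 4.53 ± 0.321. Cdkn1a, the p53 target that encodes the cell cycle inhibitor p21, rose 11.3-fold (log2 3.50, SE 0.425, adjusted p = 1.07e-06). In all genes named here for an irradiation effect the 5 irradiated arrays lay wholly on 1 side of the 5 unirradiated arrays.

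Of the 18726 genes, 5088 passed in p38WT (27.2%), 2793 higher and 2295 lower, and 2877 of them changed at least 2-fold. The majority depended on the scaling: 840 higher and 3379 lower with no scaling, 2074 and 3849 with the 75th percentile over probes detected on all arrays, an alternative added after the data had been seen. At an unadjusted p under 0.05 there were 7026. In 4643 genes (24.8%) the 5 and 5 arrays did not overlap, against 0.794% that chance would give. Among the largest rises were the interferon-induced genes Ifit3b (45.8-fold, SE 0.455, adjusted p = 1.92e-09), Ifit3 (43.6-fold, SE 0.309, adjusted p = 2.82e-12) and Ifitm1 (11.6-fold, SE 0.467, adjusted p = 3.83e-06). Slfn3 rose 17.1-fold (SE 0.365, adjusted p = 7.36e-09), and Fap, which encodes a serine protease, 16.1-fold (SE 0.343, adjusted p = 3.72e-09). Entpd3 rose 18.5-fold (SE 0.469, adjusted p = 2.86e-07) and Cldn19 12-fold (SE 0.584, adjusted p = 6.01e-05). Gdf15, a stress-induced cytokine, rose 13.4-fold (SE 0.545, adjusted p = 1.44e-05). Among the falls were Fcer2a (CD23), at least 36.2-fold (adjusted p = 6.57e-10), H2-Eb2, at least 13.5-fold (adjusted p = 3.90e-10), and Srpk3, at least 19.6-fold (adjusted p = 1.31e-07). Pla2g2d fell at least 6.88-fold (adjusted p = 5.48e-06). Dapl1 fell 45.2-fold (SE 0.389, adjusted p = 2.39e-10), Fcrla 44.1-fold (SE 0.520, adjusted p = 2.19e-08), and Tnfrsf13c, the BAFF receptor, 43.0-fold (SE 0.421, adjusted p = 6.57e-10). Fcmr, the IgM Fc receptor, fell 32.9-fold (SE 0.447, adjusted p = 7.10e-09). Bcl11a fell 34.5-fold (SE 0.466, adjusted p = 1.13e-08), with 2 of its 3 probes falling and the other at 0.383.

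Slide and dose overlapped in part. Only slide 2 held both doses of p38WT, with unirradiated array 5 alone against 3 irradiated arrays. With slide as a fixed block the p38WT effect rests on that slide, so only its size is given here. The log2 change was 2.21 for Cdkn1a, 2.01 for Cldn19, 2.71 for Entpd3 and 2.32 for Ifitm1, and these genes were no longer called. Unirradiated array 5 lay far from the other unirradiated p38WT arrays in Cdkn1a, as given below. With normexp background correction 1326 genes passed, 431 higher and 895 lower, and Pla2g2d did not (log2 -0.69, adjusted p = 0.111).

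**Figure D2:**
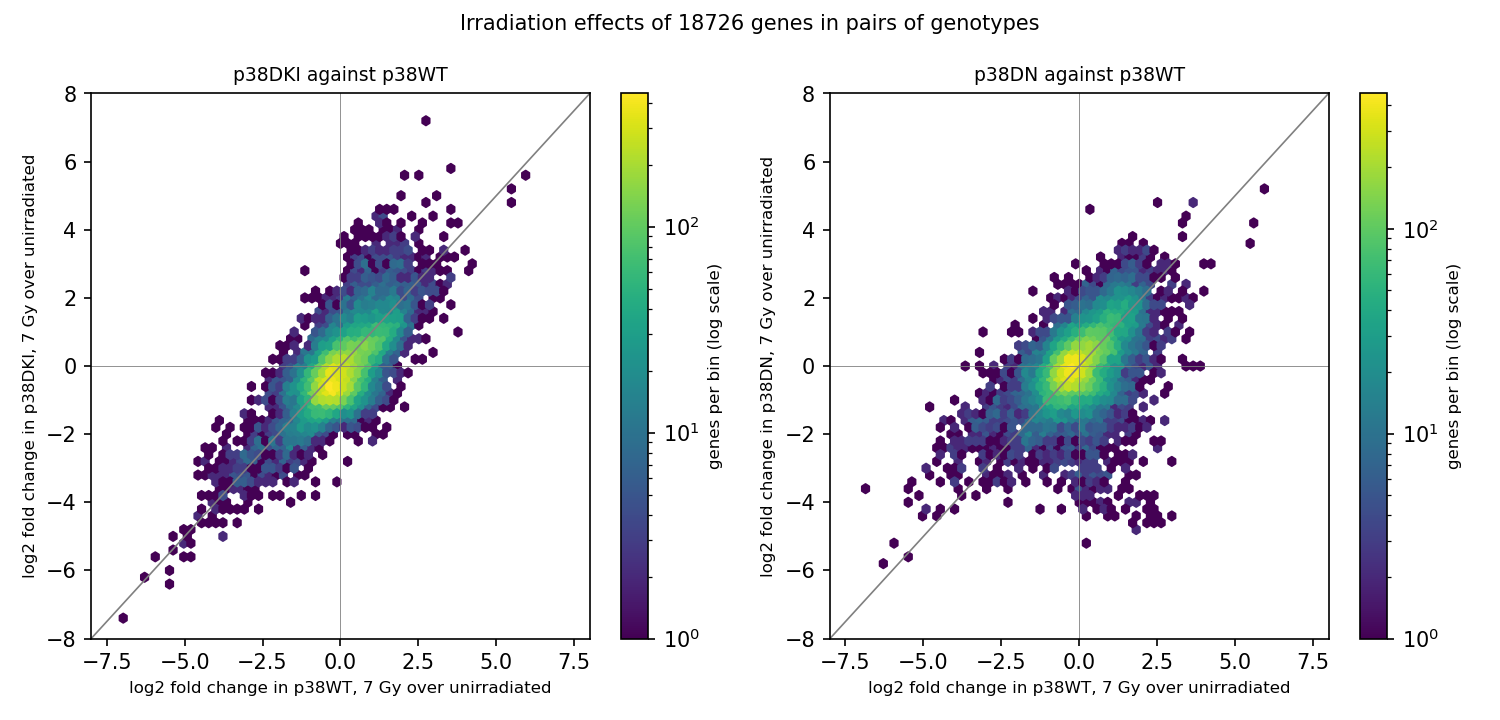
Log2 fold change by irradiation of each gene in p38DKI and in p38DN against that in p38WT, as hexagonal bins coloured by the number of genes. The correlation was 0.716 for p38DKI and 0.529 for p38DN.

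The marker lists were used to ask which blood cell transcripts were lower or higher in p38WT. Cell counts were not part of the data, so a lower list cannot separate fewer cells from less transcript per cell. Levels are relative within each array, so a higher list can also reflect the loss of other transcripts. Both limits hold for the marker lists of every genotype. Medians of lists are given relative to the median of all genes, which was -0.04. Of 25 B cell markers 22 fell and 0 rose (median log2 -3.91, adjusted p = 2.34e-27, and adjusted p = 0.0373 with an estimated correlation). Of 11 MHC class II genes, whose products present antigen, 10 fell (median -3.57, adjusted p = 1.01e-14, and 0.0373 as adjusted p with an estimated correlation). Interferon-stimulated genes rose in 27 of 35 cases (28 higher and 1 lower when adjusted over the list alone; median 1.68, adjusted p = 1.25e-21, and adjusted p = 0.0373 with an estimated correlation), Oasl1 11.2-fold and Rtp4 8.71-fold among them. Of 44 p53 target genes 26 rose and 2 fell (median 0.94, adjusted p = 5.11e-10, and adjusted p = 0.00892 with an estimated correlation). Phlda3 rose 10.3-fold, Psrc1 10-fold and Ccng1 6.32-fold. The mean of each of these 4 lists separated all 5 irradiated from all 5 unirradiated p38WT arrays.

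Further lists passed in p38WT with the preset correlation but not with an estimated one. Neutrophil markers rose in 24 of 29 cases and fell in 1 (26 and 1 over the list alone; median 2.05, adjusted p = 1.01e-14, and adjusted p = 0.0736 with an estimated correlation), with Il1r2 8.77-fold and Fpr2 5.89-fold up. Platelet markers rose in 28 of 31 (median 1.55, adjusted p = 1.16e-14, and adjusted p = 0.232 with an estimated correlation), among them Thbs1 4.31-fold. NK cell markers rose in 12 of 19 (15 over the list alone; median 1.24, adjusted p = 1.20e-06, and adjusted p = 0.35 with an estimated correlation), with the granzyme gene Gzmb 5.25-fold up. T cell markers fell in 9 of 28 (10 lower and 1 higher over the list alone; median -0.65, adjusted p = 1.81e-05, and adjusted p = 0.454 with an estimated correlation), Ccr7 13-fold and Tcf7 8.34-fold. Erythroid markers fell in 16 of 38 and rose in 3 (median -0.77, adjusted p = 0.000955, and adjusted p = 0.525 with an estimated correlation), Epor 4.06-fold up. Dendritic cell markers fell in 5 of 15 and rose in 2 (median -0.72, adjusted p = 0.0386, and adjusted p = 0.454 with an estimated correlation).

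Ribosomal protein genes fell in 33 of 63 cases in p38WT (35 over the list alone; median -0.52, adjusted p = 2.38e-09, and adjusted p = 0.454 with an estimated correlation). DNA repair genes fell in 19 of 42 and rose in 2 (23 and 2 over the list alone; median -0.55, adjusted p = 4.14e-06, and adjusted p = 0.114 with an estimated correlation), Parp1 7.60-fold down. Cell cycle genes fell in 9 of 40 and rose in 1 (median -0.65, adjusted p = 0.000542, and adjusted p = 0.454 with an estimated correlation), Nusap1 5.75-fold down. Apoptosis regulators rose in 13 of 31 and fell in 3 (14 and 4 over the list alone; median 0.51, adjusted p = 0.00782, and adjusted p = 0.327 with an estimated correlation), Bbc3 (PUMA) 3.03-fold up. Glucocorticoid-responsive genes rose in 6 of 14 and fell in 1 (8 and 2 over the list alone; median 0.73, adjusted p = 0.0201, and adjusted p = 0.327 with an estimated correlation). With slide as a fixed block the median was -3.79 for B cell markers, -3.34 for MHC class II, 1.36 for interferon-stimulated genes, 0.67 for p53 targets, 0.80 for neutrophil and 1.14 for platelet markers. Within slide 2 the medians of these lists were -3.66, -3.22, 1.49, 0.79, 0.93 and 1.27. With that block, which rests on 1 unirradiated array in p38WT, apoptosis regulators and glucocorticoid-responsive genes were no longer called. Normexp background correction ended these calls too (adjusted p = 0.973 and 0.463), as well as that of dendritic cell markers (adjusted p = 0.0559), and lowered the medians to 0.24 for p53 targets, 0.73 for interferon-stimulated genes, 0.81 for neutrophil and 0.56 for platelet markers.

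**Figure D3:**
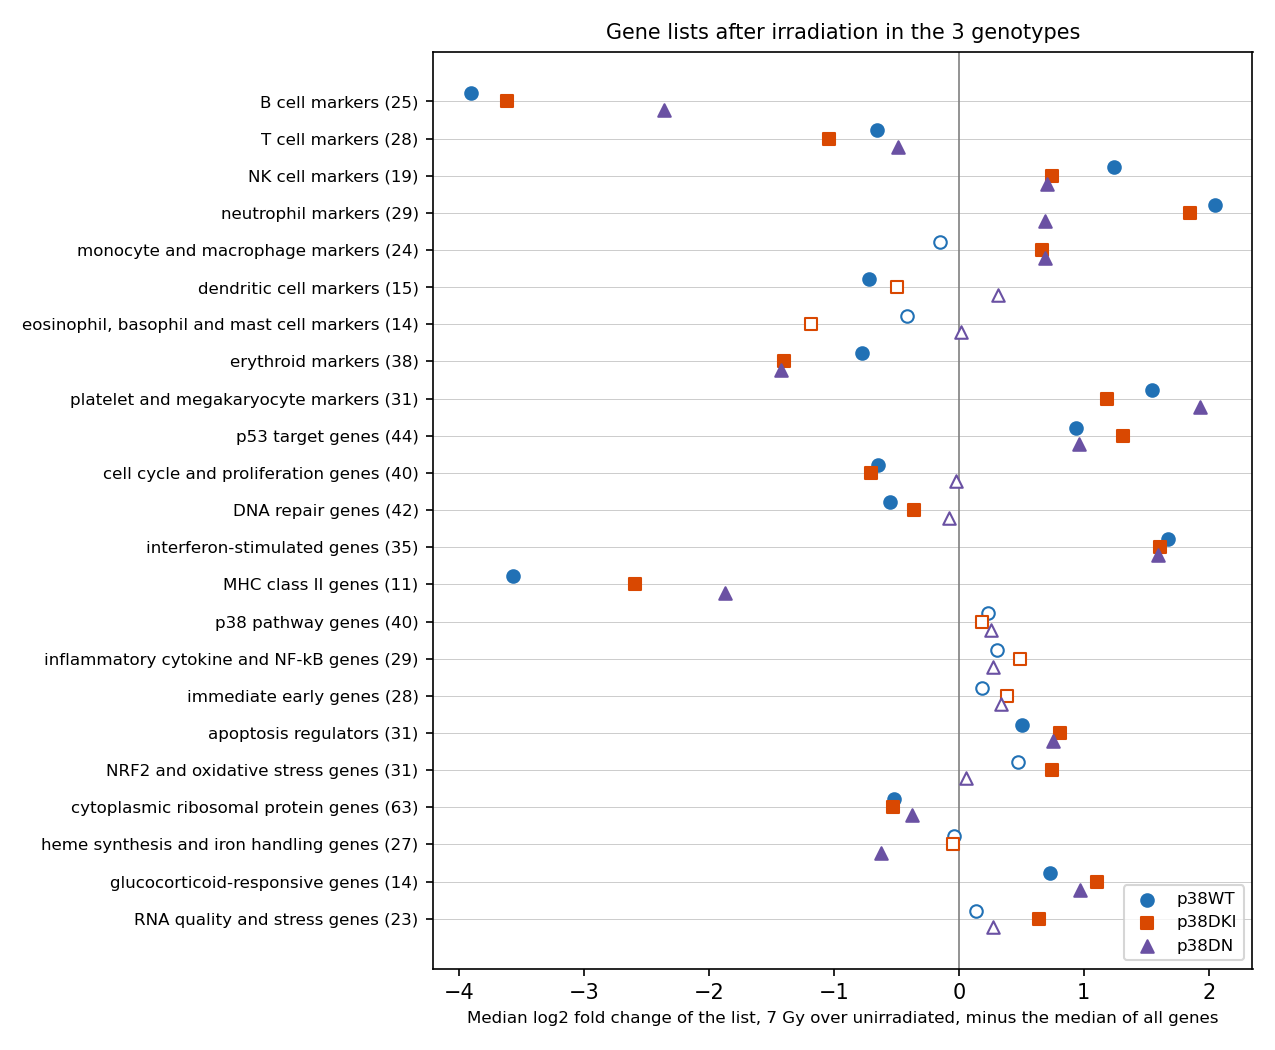
Median log2 fold change by irradiation of the measured members of each of the 23 gene lists in p38WT, p38DKI and p38DN, relative to the median of all genes, with filled symbols for lists that passed. B cell markers lay at -3.91, -3.62 and -2.36, and p53 targets at 0.94, 1.31 and 0.96.

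The second question was the same effect in p38DKI mice. The B lineage gene Vpreb3 fell 76.4-fold (SE 0.392, adjusted p = 1.67e-11), from 4.67 ± 0.414 to -1.59 ± 0.641 (SD, n = 5), and Dapl1 90.5-fold (SE 0.389, adjusted p = 8.11e-12). Serum amyloid genes, which encode acute phase proteins, had the largest rises: Saa2 153-fold (SE 1.64, adjusted p = 0.00159), Saa1 56.4-fold (SE 0.861, adjusted p = 1.58e-05) and Saa3 49.3-fold (SE 1.01, adjusted p = 0.000169). Omitting the 4 arrays highest in liver transcripts, 1 of them in this group, left Saa2 at a log2 of 5.93, Saa1 at 4.87 and Saa3 at 5.95, and all 3 still passed. This did not remove all liver transcripts. The marker excess was still -0.909 to 2.75 on the other irradiated and -1.242 to 4.28 on the unirradiated p38DKI arrays. How much of these rises stems from liver transcripts thus stays open. Interferon-induced Slfn4 rose 49.0-fold (SE 0.457, adjusted p = 1.86e-09).

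In p38DKI 5893 of 18726 genes passed (31.5%), 2215 higher and 3678 lower, against 8204 at an unadjusted p under 0.05. Of these, 3324 changed at least 2-fold. Other scalings turned the majority: 3659 higher and 1368 lower with array medians, 3820 and 759 with no scaling and 2909 and 2215 with the deposited values, against 1898 and 5035 with the 75th percentile over probes detected on all arrays. In 3679 genes (19.6%) the 5 and 5 arrays did not overlap. The median of all genes was -0.26, and list medians below are relative to it. Ifit3b rose 34.9-fold (SE 0.455, adjusted p = 6.61e-09) and Ifit3 27.2-fold (SE 0.309, adjusted p = 2.88e-11). Timp1, an inhibitor of metalloproteinases, rose at least 10.6-fold (adjusted p = 5.09e-05), Pdpn 25.9-fold (SE 0.982, adjusted p = 0.000783), Cxadr 25.1-fold (SE 0.893, adjusted p = 0.000332) and Sema3f 23.7-fold (SE 0.821, adjusted p = 0.000169). H2-Eb2 fell at least 18-fold, Srpk3 at least 32.8-fold and Pla2g2d at least 10.5-fold. Fcer2a fell 51.7-fold, Fcmr 48.4-fold, Fcrla 44.2-fold, Chst3 37.6-fold and Tnfrsf13c 32-fold.

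Of 25 B cell markers 24 fell in p38DKI (median log2 -3.62, adjusted p = 7.07e-23, and adjusted p = 0.0591 with an estimated correlation), and all 11 MHC class II genes did (median -2.59, adjusted p = 3.34e-11, and adjusted p = 0.0912 with an estimated correlation). The p53 targets rose in 25 of 44 and fell in 5 (25 and 6 over the list alone; median 1.31, adjusted p = 3.66e-11, and adjusted p = 0.00473 with an estimated correlation). Interferon-stimulated genes rose in 26 of 35 and fell in 2 (27 and 3 over the list alone; median 1.61, adjusted p = 3.63e-19, and adjusted p = 0.0591 with an estimated correlation). Erythroid markers fell in 27 of 38 and rose in 1 (29 and 2 over the list alone; median -1.40, adjusted p = 1.82e-09, and adjusted p = 0.274 with an estimated correlation). T cell markers fell in 20 of 28 (22 over the list alone; median -1.04, adjusted p = 3.27e-08, and adjusted p = 0.274 with an estimated correlation), Cd8b1 19.1-fold. Ribosomal protein genes fell in 49 of 63 (56 over the list alone; median -0.53, adjusted p = 7.74e-13, and adjusted p = 0.274 with an estimated correlation). Cell cycle genes fell in 20 of 40 (22 over the list alone; median -0.70, adjusted p = 8.08e-06, and adjusted p = 0.28 with an estimated correlation). DNA repair genes fell in 19 of 42 and rose in 1 (21 and 1 over the list alone; median -0.36, adjusted p = 0.000287, and adjusted p = 0.234 with an estimated correlation).

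Neutrophil markers rose in 20 of 29 cases in p38DKI and fell in 1 (21 and 2 over the list alone; median 1.85, adjusted p = 3.34e-11, and adjusted p = 0.133 with an estimated correlation). Platelet markers rose in 13 of 31 (18 over the list alone; median 1.19, adjusted p = 4.13e-10, and adjusted p = 0.274 with an estimated correlation). NK cell markers rose in 4 of 19 (median 0.75, adjusted p = 0.000629, and adjusted p = 0.449 with an estimated correlation). Monocyte markers rose in 6 of 24 and fell in 4 (7 and 4 over the list alone; median 0.67, adjusted p = 0.0435, and adjusted p = 0.507 with an estimated correlation). Glucocorticoid-responsive genes rose in 7 of 14 (median 1.11, adjusted p = 0.000178, and adjusted p = 0.0912 with an estimated correlation). Apoptosis regulators rose in 11 of 31 and fell in 3 (12 and 3 over the list alone; median 0.81, adjusted p = 0.000287, and adjusted p = 0.155 with an estimated correlation). Genes of the NRF2 response rose in 12 of 31 and fell in 6 (13 and 8 over the list alone; median 0.75, adjusted p = 0.0152, and adjusted p = 0.298 with an estimated correlation). The list of RNA quality and stress genes rose in 8 of 23 and fell in 2 (8 and 3 over the list alone; median 0.64, adjusted p = 0.000629, and adjusted p = 0.274 with an estimated correlation), with the heat shock gene Hspb1 15.6-fold up. Once the 4 arrays highest in liver transcripts, among them p38DKI irradiated 2, were left out, the median was 1.18 for NK cell markers (adjusted p = 7.13e-09) and 0.36 for NRF2 genes (adjusted p = 0.0151). With the liver marker level as a covariate it was 0.37 for NRF2 genes (adjusted p = 0.0295) and 0.31 for RNA quality genes (adjusted p = 0.0166). The T cell, cell cycle and ribosomal protein scores were lowest on p38DKI irradiated array 2, at -2.304, -1.619 and -0.884. They reached 0.031, 0.052 and 0.279 on other irradiated p38DKI arrays. The sizes of these list falls in p38DKI thus rest in part on array 2.

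With slide as a fixed block the p38DKI effect rests on slide 4, with irradiated array 1 alone against 3 unirradiated arrays. Only its size is therefore given here. The log2 change was 3.68 for Saa1, 6.28 for Saa2, 4.59 for Saa3, 4.91 for Cxadr and -4.0 for Pla2g2d, and the monocyte median was 0.39. These genes and this list were no longer called. The blocked medians were -3.59 for B cell markers, -2.93 for MHC class II, 1.31 for interferon-stimulated genes, 1.12 for p53 targets, 1.58 for neutrophil and 2.08 for platelet markers. Within slide 4, the only slide with both doses of p38DKI, they were -3.65, -2.98, 1.25, 1.06, 1.52 and 2.02. With normexp background correction 1381 genes passed, 660 higher and 721 lower, Timp1 not among them (log2 1.17, adjusted p = 0.0609), the call of ribosomal protein genes ended (adjusted p = 0.583), and the medians were -2.29 for B cell markers and 0.57 for p53 targets. Without the 4 arrays highest in liver transcripts 2879 genes were higher and 3121 lower.

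The third question was the effect of irradiation in p38DN mice. Slfn4 rose most (38.6-fold, SE 0.457, adjusted p = 6.20e-09), and the p53 targets Gdf15 (26.8-fold, SE 0.545, adjusted p = 6.56e-07), Cdkn1a (20.2-fold, SE 0.425, adjusted p = 5.70e-08) and Phlda3 (14.6-fold, SE 0.269, adjusted p = 1.57e-10) rose as well. Phlda3 went from 1.06 ± 0.262 to 4.93 ± 0.181 (SD, n = 5). The scavenger receptor gene Marco rose 29.4-fold (SE 0.778, adjusted p = 4.05e-05), Saa3 28.9-fold (SE 1.01, adjusted p = 0.000691) and the B cell chemokine gene Cxcl13 25.2-fold (SE 0.806, adjusted p = 0.0001). Vpreb3 fell 59.0-fold (SE 0.392, adjusted p = 1.28e-10) and Dapl1 49.6-fold (SE 0.389, adjusted p = 1.57e-10).

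In p38DN 5226 of 18726 genes passed (27.9%), 3233 higher and 1993 lower, against 7317 at an unadjusted p under 0.05. Of these, 3223 changed at least 2-fold. Here too the majority turned, to 2588 higher and 3025 lower with the 75th percentile over probes detected on all arrays, 2301 and 2547 with the deposited values and 2556 and 2913 without the 4 arrays highest in liver transcripts. In 3737 genes (20%) the arrays did not overlap. Ifit3b rose 18.2-fold (SE 0.455), Oas2 18.1-fold (SE 0.297) and the death receptor gene Tnfrsf10b at least 5.59-fold. Fcer2a fell at least 26-fold. Fcmr fell 22.1-fold (SE 0.447), Kmo 21.3-fold (SE 0.93), Ell3 19.0-fold (SE 0.432), Chst3 18.3-fold (SE 0.348) and Ccr6 17.4-fold (SE 0.435). Scd1 fell 18.9-fold (SE 0.808) and Cyp4a31 18.4-fold (SE 1.119). Kmo, Scd1 and Cyp4a31 had the largest SE of these falls, and unirradiated p38DN arrays 2, 4 and 5 were rich in liver transcripts. Cyp4a31, a cytochrome P450 gene, no longer passed without the 4 arrays highest in liver transcripts (log2 -0.83, adjusted p = 0.288). With normexp background correction 445 genes passed, 388 higher and 57 lower, and Cyp4a31, Ell3, Ifit3b, Kmo, Scd1 and Tnfrsf10b did not.

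All 31 platelet markers rose in p38DN (median log2 1.93, adjusted p = 4.13e-18, and adjusted p = 0.123 with an estimated correlation), Thbs1 9.95-fold and Itga2b 5.66-fold. B cell markers fell in 23 of 25 (median -2.36, adjusted p = 4.13e-18, and adjusted p = 0.0902 with an estimated correlation), and MHC class II genes in all 11 (median -1.87, adjusted p = 5.13e-09, and adjusted p = 0.121 with an estimated correlation). The p53 targets rose in 25 of 44 and fell in 1 (25 and 2 over the list alone; median 0.96, adjusted p = 1.16e-11, and adjusted p = 0.0033 with an estimated correlation), Zmat3 8.33-fold up. Interferon-stimulated genes rose in 27 of 35 and fell in 3 (28 and 3 over the list alone; median 1.60, adjusted p = 9.11e-16, and adjusted p = 0.0902 with an estimated correlation). Erythroid markers fell in 26 of 38 and rose in 3 (27 and 3 over the list alone; median -1.42, adjusted p = 4.99e-10, and adjusted p = 0.296 with an estimated correlation). Genes of heme synthesis and iron handling fell in 12 of 27 and rose in 3 (median -0.62, adjusted p = 0.000105, and adjusted p = 0.101 with an estimated correlation), Glrx5 7.14-fold down.

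Apoptosis regulators rose in 15 of 31 cases in p38DN and fell in 3 (17 and 3 over the list alone; median 0.75, adjusted p = 0.000151, and adjusted p = 0.121 with an estimated correlation), Bbc3 5.12-fold up. Glucocorticoid-responsive genes rose in 9 of 14 (median 0.97, adjusted p = 6.30e-05, and adjusted p = 0.0902 with an estimated correlation). Monocyte markers rose in 10 of 24 and fell in 2 (11 and 2 over the list alone; median 0.69, adjusted p = 0.0337, and adjusted p = 0.698 with an estimated correlation). Neutrophil markers rose in 8 of 29 and fell in 1 (median 0.69, adjusted p = 0.0181, and adjusted p = 0.698 with an estimated correlation). NK cell markers rose in 4 of 19 (median 0.71, adjusted p = 0.0363, and adjusted p = 0.699 with an estimated correlation). T cell markers fell in 7 of 28 and rose in 1 (median -0.48, adjusted p = 0.000855, and adjusted p = 0.698 with an estimated correlation), Ccr7 14.4-fold down. Ribosomal protein genes fell in 16 of 63 (14 over the list alone; median -0.38, adjusted p = 2.37e-06, and adjusted p = 0.698 with an estimated correlation), while normexp background correction turned their median to 0.155. Without the 4 arrays highest in liver transcripts the monocyte (adjusted p = 0.0705) and NK cell (adjusted p = 0.626) lists no longer passed, and the median of p53 targets was 1.46. Normexp background correction lowered the medians to -1.13 for B cell markers, -0.82 for MHC class II, 0.75 for interferon-stimulated genes and 0.38 for p53 targets.

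Each of slides 6 to 10 held 1 array of either dose of p38DN. With slide as a fixed block the median was -2.36 for B cell markers, -1.87 for MHC class II, 1.60 for interferon-stimulated genes, 0.96 for p53 targets, 0.69 for neutrophil and 1.93 for platelet markers. Within the slides, B cell medians were -2.79, -1.94, -3.74, -2.19 and -1.68, and those of p53 targets 1.18, 1.25, 1.47, 1.16 and 1.04. Interferon-stimulated genes had medians of 1.32, 0.92, 1.75, 1.59 and 1.84, MHC class II genes -2.90, -1.64, -2.29, -1.01 and -1.84, and platelet markers 2.31, 1.40, 1.78, 1.35 and 2.54. The neutrophil median was 1.04, 0.87, -0.64, 0.39 and 1.09.

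**Figure D4:**
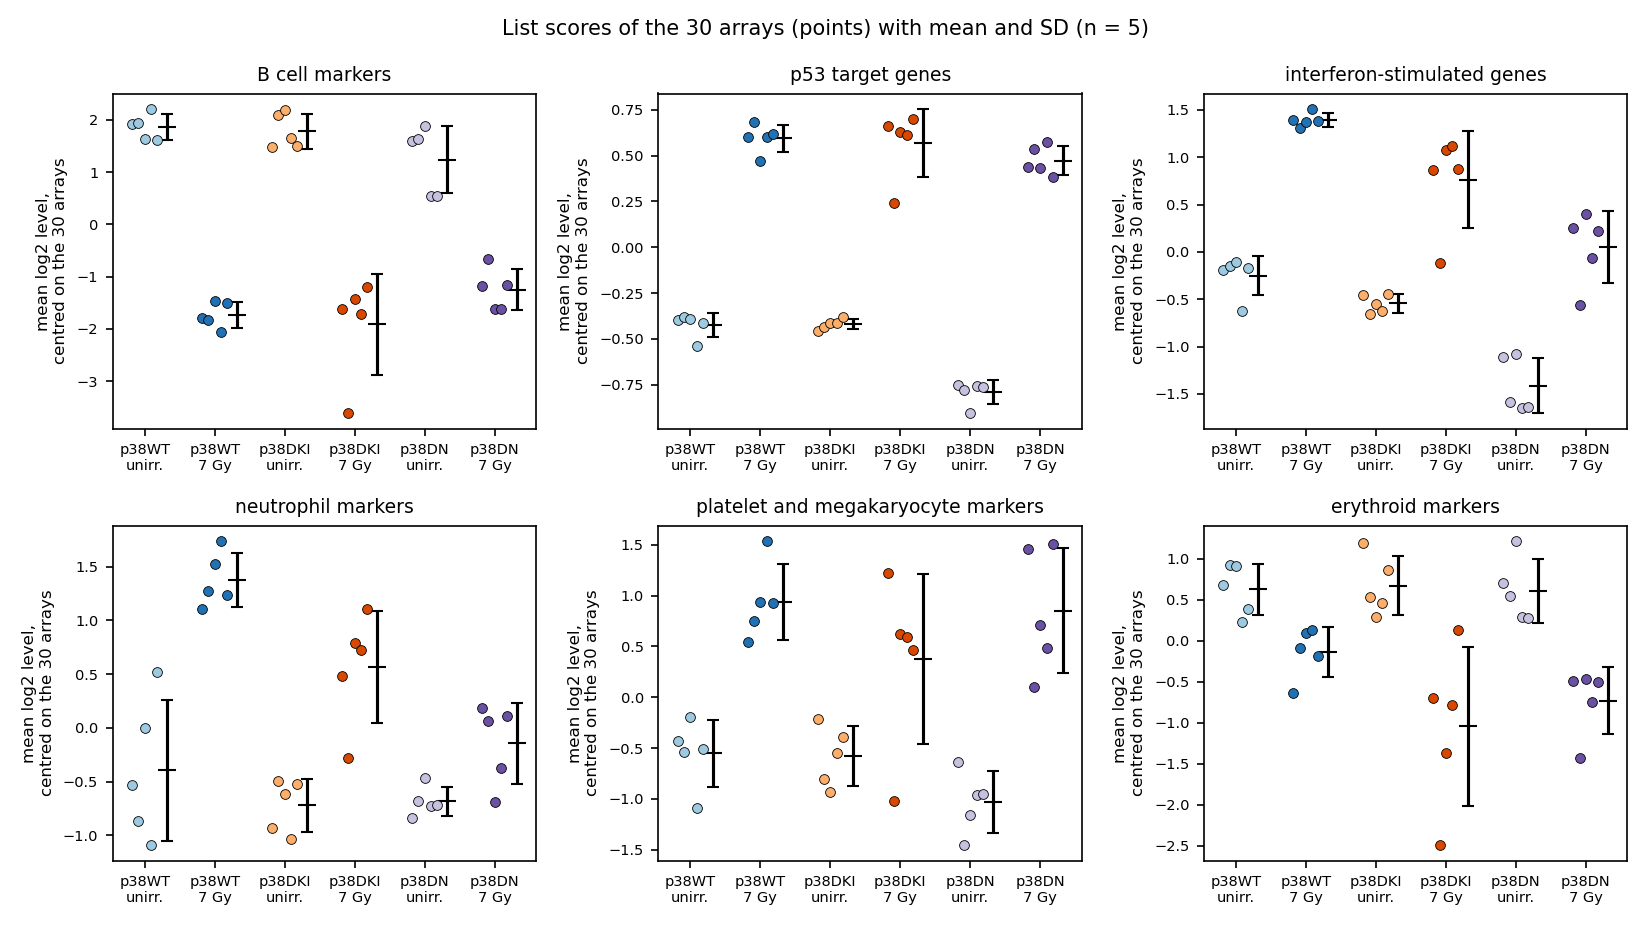
Mean log2 level of 6 gene lists on each array, centred on the 30 arrays, by group, 1 point per array with the group mean. The p53 target score was -0.42 and 0.59 in p38WT, -0.42 and 0.57 in p38DKI and -0.79 and 0.47 in p38DN without and with irradiation.

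How far the genotypes shared the response was asked next. Log2 fold changes correlated at 0.716 (rank correlation 0.614) between p38WT and p38DKI, 0.529 (0.49) between p38WT and p38DN and 0.47 (0.507) between p38DKI and p38DN, over 18726 genes. Of 2976 genes called in both p38WT and p38DKI, 99.2% had the same direction, with 1430 both higher against 330 by independent calls and 1521 both lower against 451. For p38WT and p38DN 98.7% of 2690 shared direction, with 1712 against 482 higher and 944 against 244 lower. For p38DKI and p38DN 99.1% of 2585 did, with 1329 against 382 higher and 1234 against 391 lower. In all 3 genotypes 1017 genes rose and 831 fell, of 9808 called in at least 1. Normexp background correction lowered the correlation of p38WT to 0.354 with p38DKI and 0.2 with p38DN, and without the 4 arrays highest in liver transcripts that of p38DKI with p38DN was 0.774.

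Whether p38DKI altered the response was tested as the difference between irradiation effects, p38DKI minus p38WT. Only Olfr1402, an olfactory receptor gene, passed (log2 difference -2.01, SE 0.339, adjusted p = 0.047), while 2613 genes had an unadjusted p under 0.05. The median difference over all genes was -0.22, and list medians are relative to it. Erythroid markers lay lower (median -0.76, adjusted p = 4.69e-05, and adjusted p = 0.874 with an estimated correlation) and monocyte markers higher (median 0.58, adjusted p = 0.0198, and adjusted p = 0.874 with an estimated correlation), with 0 of 38 and 0 of 24 members past the threshold. Normexp background correction turned the direction of the erythroid test (median -0.06, adjusted p = 0.946). Their medians were -0.55 and 0.58 once slide was a fixed block. The count of 1 became 0 without p38WT unirradiated 1, 2, 3 or 4, p38WT irradiated 1, 2, 3 or 4, p38DKI unirradiated 1, 2 or 4, or p38DKI irradiated 2, 3 or 4, and in a fit on only these 4 groups. Olfr1402 was also lost without p38DKI unirradiated 5 (adjusted p = 0.0688). The count became 2 without p38DKI irradiated 1, 10 without p38WT irradiated 5, 40 without p38WT unirradiated 5 and 59 without p38DKI irradiated 5.

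The same difference was taken for p38DN minus p38WT. Irradiation effects were more positive in p38DN for Clec10a, which encodes a lectin of macrophages and dendritic cells (3.50, SE 0.763, adjusted p = 0.0228), Rtn1 (3.38, SE 0.621, adjusted p = 0.012) and Ddr1 (3.09, SE 0.643, adjusted p = 0.0165). Rtn1 and Ddr1 were well above background on 0 of 5 unirradiated p38DN arrays, so their sizes are uncertain. Mcpt8 (3.57) and Cyp11a1 (2.88) passed too, but were well above background on 0 of 5 p38DN arrays of either dose. These values thus reflect the fall in p38WT, for Mcpt8 from -0.85 ± 0.470 to -4.47 ± 0.938 (SD, n = 5), and no effect was measured in p38DN. Irradiation effects were more negative for H2-Q10 (-4.28, SE 1.01, adjusted p = 0.0331), Acot1 (-3.52, SE 0.880, adjusted p = 0.0408), Csta2 (-3.41, SE 0.533, adjusted p = 0.0027), S100a2 (-3.41, SE 0.767, adjusted p = 0.0256) and Steap4 (-3.11, SE 0.705, adjusted p = 0.0263). Without the 4 arrays highest in liver transcripts H2-Q10 (-1.84, adjusted p = 0.0803), Acot1 (-1.20, adjusted p = 0.253) and Steap4 (-2.64, adjusted p = 0.0655) no longer passed. With normexp background correction 0 of these 10 genes passed, and with slide as a fixed block 1 did. The p53 target Zmat3 had a larger rise in p38DN (1.67, SE 0.290, adjusted p = 0.00883), and Ifit3 a smaller one (-1.95, SE 0.437, adjusted p = 0.0253). Tnfrsf10b passed (1.99), but was well above background on 0 of 5 unirradiated p38DN arrays, and normexp background correction turned the difference to -0.477.

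In this comparison 316 genes passed, 195 higher and 121 lower, against 3542 at an unadjusted p under 0.05. Neutrophil markers were lower (5 of 29 members, 12 over the list alone, median -1.22, adjusted p = 1.85e-10) and B cell markers higher (0 of 25, 9 over the list alone, median 1.26, adjusted p = 2.63e-05), as were MHC class II genes (0 of 11, 6 over the list alone, median 1.41, adjusted p = 0.000423), all 3 with adjusted p = 0.623 with an estimated correlation. A fixed block for slide gave medians of -0.10, 1.21 and 1.42 for these lists, ended the neutrophil call (adjusted p = 0.488) and left 2 genes in place of 316. Without the 4 arrays highest in liver transcripts the B cell median was 0.79, and with the liver marker level as a covariate it was 0.77 and that of MHC class II genes 0.90. A fit on only these 4 groups gave 526 genes, 267 higher and 259 lower. The majority turned to 204 higher and 501 lower without those arrays, 271 and 733 with the covariate and 97 and 172 with the deposited values, and was 273 and 13 with no scaling. Normexp background correction left 1 gene. The count was 135, 167 and 143 without p38DN unirradiated 2, 4 and 5, and 92 and 106 without p38DN irradiated 2 and 4. It was 92, 123 and 136 without p38WT unirradiated 1, 2 and 3, 73 higher and 41 lower without p38WT unirradiated 4, and 149 and 145 without p38WT irradiated 2 and 4.

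Between p38DN and p38DKI the irradiation effect differed for 172 genes, 132 higher and 40 lower, against 4199 at an unadjusted p under 0.05. The median over all genes was 0.32. The T cell gene Cd8b1 (log2 difference 3.36, SE 0.593, adjusted p = 0.0074) and Sptb (2.88, SE 0.675, adjusted p = 0.0391) were higher. Mcpt8 (4.06), Crisp3 (3.15) and Klk1b27 (2.86) passed as well, but were well above background on 0 of 5 p38DN arrays of either dose, so that no effect was measured in p38DN. Stbd1 (-5.40, SE 1.32, adjusted p = 0.0468), Il1rap (-5.33, SE 1.16, adjusted p = 0.025), H2-Q10 (-4.21, SE 1.01, adjusted p = 0.0419), Klhl13 (-3.55, SE 0.545, adjusted p = 0.002) and Rmdn2 (-3.51, SE 0.651, adjusted p = 0.00981) were lower. Il1rap and Rmdn2 were well above background on 0 of 5 irradiated p38DN arrays and Klhl13 on 0 of 5 unirradiated p38DKI arrays, so their sizes are uncertain. The majority turned to 13 higher and 26 lower with array medians, 8 and 14 with no scaling and 17 and 59 with the deposited values. Without the 4 arrays highest in liver transcripts 38 genes passed, 14 higher and 24 lower, and of these 10 genes only Mcpt8, Crisp3 and Klhl13 did. A fixed block for slide left 0 genes, and a fit on only these 4 groups 26, with 7 of the 10 named genes lost. Normexp background correction left 1 gene, and 0 of these 10 passed. The count was 75, 77, 59 and 94 without p38DKI unirradiated 2, 3, 4 and 5, 313 without p38DKI irradiated 1, and 76 higher and 28 lower without p38DKI irradiated 5. It was 682, 81, 494, 68 and 49 without p38DN unirradiated 1, 2, 3, 4 and 5, 106, 83 and 97 without p38DN irradiated 1, 4 and 5, and 89 higher and 24 lower without p38DN irradiated 2.

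Before irradiation p38DKI and p38WT differed at few genes, and the largest difference lay on chromosome 15. Sult4a1, a sulfotransferase gene at 83906546 to 83906605, was 118-fold higher in p38DKI (log2 6.88, SE 0.405, adjusted p = 1.07e-11), at 4.22 ± 0.294 against -2.66 ± 0.407 (SD, n = 5), with 3 of 3 probes higher. Mapk11, which encodes p38 beta (88973159 to 88973218), was 2.71-fold higher (log2 1.44, SE 0.275, adjusted p = 0.0247), at 1.63 ± 0.3 against 0.19 ± 0.235. Mapk14, which encodes p38 alpha, did not pass (log2 -0.71, SE 0.227, adjusted p = 0.311), and its probes disagreed in direction. Tomm22, a gene of mitochondrial protein import at 79503096, was 3.16-fold lower (SE 0.205, adjusted p = 9.64e-05).

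In all 19 genes passed, 16 higher and 3 lower, against 1382 at an unadjusted p under 0.05. The split depended on the scaling: 6 higher and 6 lower with array medians, 11 and 7 with quantiles, 4 and 4 with the deposited values and 3 and 4 with no scaling. In 528 genes (2.8%) the arrays did not overlap, where chance gives 0.794%. Fn3krp was 10.4-fold higher (SE 0.585, adjusted p = 0.00856), Dnaaf5 at least 5.58-fold (adjusted p = 0.00346), Arhgap8 at least 3.03-fold (adjusted p = 0.000583) and Patz1 3.77-fold (SE 0.340, adjusted p = 0.0115). Nefh was 10.1-fold lower (SE 0.560, adjusted p = 0.00637) and Pes1 3.21-fold (SE 0.237, adjusted p = 0.000598), each by 1 of its 2 probes, and Pes1 turned to 0.217 with the deposited values. Apart from Mapk11 itself, 3 of 17 placed genes lay within 10 Mb of Mapk11 against 1.32% of all genes, 13.4 times as many (permutation p = 0.00135). Closeness of called genes was not particular to Mapk11. Patz1, Pes1 and Nefh lie together on chromosome 11, at 3194546, 3879948 and 4838758. Only the surroundings of Mapk11 and Mapk14 were tested. Slide as a fixed block left 2 genes, and of the 8 named here other than Mapk11 and Mapk14 only Sult4a1 passed. The differences did not all shrink there: Tomm22 was at a log2 of -2.14 (129% of its value), Arhgap8 at 2.33 (86.7%) and Fn3krp at 3.86, while Nefh was at -1.27 and Pes1 at -0.55. Normexp background correction left 1 gene in place of 19, and 7 of these 8 genes no longer passed, Tomm22 at -1.38 and Arhgap8 at 0.80. The count of 19 became 9 without p38DKI unirradiated 4, 10 without p38WT unirradiated 1 or 2, 11 without p38WT unirradiated 3 and 31 without p38WT unirradiated 5.

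Several lists passed for p38DKI before irradiation although at most 1 member did. Interferon-stimulated genes lay lower (0 of 35, median -0.41, adjusted p = 1.91e-09, and adjusted p = 0.419 with an estimated correlation), as did neutrophil markers (0 of 29, median -0.48, adjusted p = 9.45e-06, and adjusted p = 0.419 with an estimated correlation). Ribosomal protein genes lay higher (0 of 63, median 0.18, adjusted p = 9.51e-07, and adjusted p = 0.644 with an estimated correlation), and normexp background correction turned their median to -0.331. For these 3 lists the medians with slide as a fixed block were -0.79, -1.76 and 0.55, and no slide held both genotypes at the same dose.

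**Figure D5:**
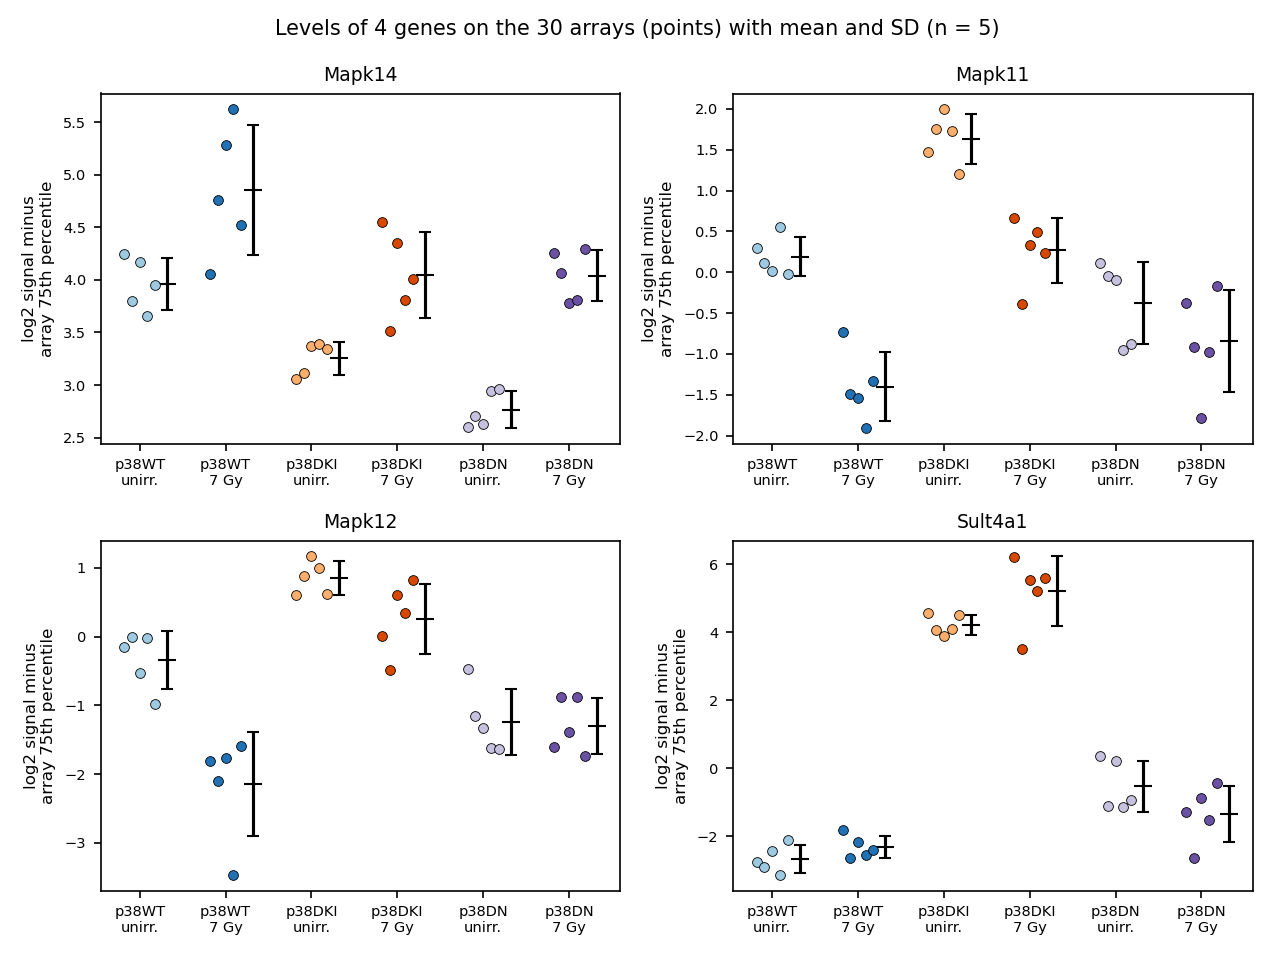
Levels of p38 genes and Sult4a1 on each array (log2 relative to the 75th percentile) by group, 1 point per array with the group mean. Sult4a1 averaged 4.22 and 5.21 in p38DKI against -2.66 and -2.32 in p38WT.

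In the main fit more genes differed between p38DKI and p38WT after irradiation (815) than before it (19). The order turned in a fit on only these groups (1 against 19), with array weights (413 against 1025) and with the liver marker level as a covariate. With normexp background correction it was 1 against 1. The difference of irradiation effects, which tests this directly, called 1 gene. After irradiation Sult4a1 was 184-fold higher (log2 7.52, SE 0.405, adjusted p = 1.14e-12). The p38 genes diverged: Mapk12 was 5.30-fold higher (SE 0.308, adjusted p = 9.62e-05), Mapk11 3.17-fold higher (SE 0.275, adjusted p = 0.00298), Mapk13 lower (log2 -1.58, SE 0.309, adjusted p = 0.00686) and Mapk14 1.75-fold lower (SE 0.227, adjusted p = 0.041), with 1 of 2 Mapk14 probes lower. Mapk12 lies next to Mapk11 on chromosome 15, at 88961267 to 88961326. Interferon-stimulated genes were lower in 8 of 35 cases (19 lower and 1 higher over the list alone; median -0.50, adjusted p = 5.78e-07, and adjusted p = 0.95 with an estimated correlation), Irf7 by a log2 of -1.50 (SE 0.322, adjusted p = 0.0118).

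Of the 815 genes that passed 213 were higher and 602 lower, against 4621 at an unadjusted p under 0.05. With no scaling 68 were higher and 8 lower, with the deposited values 140 and 181, and with the 75th percentile over probes detected on all arrays 312 and 357. In 1223 genes (6.5%) the arrays did not overlap, and the median of all genes was -0.10. Slco1b2, a transporter gene of liver, was at least 10.4-fold higher (adjusted p = 0.0323), on arrays with liver transcripts. Mrc1 (6.90-fold, SE 0.75, adjusted p = 0.0347) and Fkbp14 (4.63-fold, SE 0.425, adjusted p = 0.00602) were higher. Apol11b (6.19-fold, SE 0.421, adjusted p = 0.00255), Il22ra2 (5.30-fold, SE 0.516, adjusted p = 0.0118), Apol10b (4.93-fold, SE 0.426, adjusted p = 0.00511), the red cell membrane gene Epb42 (4.60-fold, SE 0.439, adjusted p = 0.00727) and Fezf1 (4.2-fold, SE 0.545, adjusted p = 0.0318) were lower. Erythroid markers were lower in 8 of 38 (12 over the list alone; median -0.68, adjusted p = 5.78e-07, and adjusted p = 0.95 with an estimated correlation) and neutrophil markers in 6 of 29 (16 over the list alone; median -0.81, adjusted p = 2.62e-06, and adjusted p = 0.95 with an estimated correlation). Apart from Mapk11, 25 of 802 placed genes lay within 10 Mb of it, 2.37 times the share of all genes (permutation p = 8.0e-05), and 37 lay within 10 Mb of Mapk14, 1.79 times the share (permutation p = 0.00036). Before irradiation 0 of 18 placed genes lay within 10 Mb of Mapk14.

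A fit on only the arrays of these 2 groups gave 1 gene in place of 815, and 9 of the 10 named genes, all but Sult4a1, no longer passed, Mapk12 with an adjusted p of 0.186. Only 1 gene passed with slide as a fixed block after irradiation, and Mapk12 was at 2.35 (adjusted p = 1) and Epb42 at -2.01 (adjusted p = 1). The blocked medians were -0.75 for interferon-stimulated genes, -0.23 for erythroid and -1.19 for neutrophil markers. Normexp background correction left 1 gene and ended the interferon (adjusted p = 0.865), erythroid (adjusted p = 0.0856) and neutrophil calls (adjusted p = 0.519). The erythroid median was -0.40 without the 4 arrays highest in liver transcripts, -0.42 with the liver marker level as a covariate and -0.39 with array weights. The count of 815 became 251 without p38DKI irradiated 2 and 426, 492, 535 and 315 without p38WT irradiated 1, 2, 3 and 4.

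Between p38DN and p38WT 10177 genes differed before irradiation (3513 higher, 6664 lower, median of all genes -0.38) and 8058 after it (3141 higher, 4917 lower, median -0.19). The majorities turned with the deposited values, to 4722 higher and 4072 lower before and 3779 and 3404 after irradiation. With the 75th percentile over probes detected on all arrays they were 4404 and 4651 before and 4583 and 2986 after it, and with no scaling 2360 and 8683 before and 2772 and 2870 after it. Liver genes led the rises before irradiation, with Alb (albumin) at least 1391-fold, Rbp4 at least 716-fold and Serpina1a at a log2 of 11.98 (SE 1.96, adjusted p = 1.17e-05). Alb was at 6.85 ± 4.17 in p38DN (SD, n = 5), and 3 of the 5 arrays were among those highest in liver transcripts. NK cell markers were lower in 16 of 19 cases before (18 over the list alone; median -1.25, adjusted p = 0.00105, and adjusted p = 0.884 with an estimated correlation) and in all 19 after irradiation (median -1.97, adjusted p = 1.85e-08, and adjusted p = 0.912 with an estimated correlation). With the liver marker level as a covariate the NK cell call before irradiation ended (median -0.30, adjusted p = 0.232), and the interferon median there was -0.47. Klrg1 was 45.7-fold (SE 0.468, adjusted p = 1.38e-09) and the granzyme gene Gzma 31.6-fold lower (SE 0.480, adjusted p = 1.08e-08) after irradiation. Interferon-stimulated genes were lower in 27 of 35 before (median -0.72, adjusted p = 0.000134, and adjusted p = 0.884 with an estimated correlation) and 30 after (31 over the list alone; median -1.10, adjusted p = 2.29e-09, and adjusted p = 0.912 with an estimated correlation). Mapk14 was lower before (log2 -1.20, SE 0.227, adjusted p = 7.76e-05) and after irradiation (-0.81, SE 0.227, adjusted p = 0.00491), on both its probes. Batch and group cannot be told apart here, so slide as a fixed block and scan date as a block give no value. Slide as a random block gave 10615 genes before and 8281 after irradiation, and does not separate batch either. With normexp background correction 934 genes passed after irradiation.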

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

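Transcripts of liver on 4 of the 30 arrays (p38DKI irradiated 2 and p38DN unirradiated 2, 4 and 5) were examined with tests chosen only after the result was seen. The arrays were picked for the highest liver marker level, so 1 of the values restates that choice and decides nothing. At least 97.8% of the markers lay over 2 (log2) above the median of the other arrays on each. The mean marker level ranged over 10.79 within 1 group. Scaling of the arrays is argued against by an excess of at least 3.73 over 6 scalings. Genotype or dose alone is argued against only for the full excess on these 4 arrays, as other arrays of their groups lay far lower. The excess was 9.88 on p38DKI irradiated array 2, against -0.909 to 2.75 on the others of its group. On p38DN unirradiated arrays 2, 4 and 5 it was 7.802 to 8.772, against 1.981 and 1.185 on arrays 1 and 3. Arrays 1 and 3 still lay above all p38WT arrays, so a smaller part shared by the p38DN group or its batch stays open. RNA from liver cannot be told apart from an effect of genotype or irradiation that arose in some mice only, and batch stays open too. The excess was at most 0.226 on the p38WT arrays, and ranged from -0.567 to 4.03 on the p38DN irradiated, -1.242 to 4.28 on the p38DKI unirradiated and, without array 2, -0.909 to 2.75 on the p38DKI irradiated arrays.

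Genes that differed between p38DKI and p38WT and lie near Mapk11 were the second pattern, and of its tests the one on linked DNA was chosen after the result was seen. DNA linked to Mapk11 that differs between the lines could account for it: called genes were 13.4 times as frequent within 10 Mb as all genes before irradiation but 2.37 times after it, too few to meet the bound of 5 and too many to meet that of 2. Slide cannot be told apart from it, since the genes kept a median of 84% of their log2 fold change with slide as a fixed block (bootstrap range 49.5 to 95.8) and 2 of 28 changed sign. The bootstrap drew pairs of gene and comparison that share arrays, so its range leaves out the spread between mice. The blocked values rest on p38WT unirradiated array 5 before irradiation and on p38DKI irradiated array 1 after it. A single faulty probe is argued against for the 4 of 26 genes with another probe, where 8 other probes moved in the same direction in 100% of 10 comparisons. An effect of the altered p38 genes themselves stays open as untested.

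Irradiation effects that differed between p38DN and p38WT were the third pattern, and its tests were set before their values were seen. Liver transcripts in p38DN unirradiated arrays 2, 4 and 5 stay open as a cause. Without these arrays the median difference of the 316 genes was 94.9% of its value (1.53 against 1.61), and all 316 kept direction. But these genes were called with those arrays included, and the refit shares all other arrays, so this cannot decide. In the refit 77 genes passed, 51 of them shared. Omitting the 4 arrays highest in liver transcripts turned the split from 195 higher and 121 lower to 204 and 501. The array added to the omission, p38DKI irradiated 2, is not in this comparison. It enters only through the spread estimated jointly over all groups, so the counts with and without it differ through that spread. Smaller fold changes on the arrays of the earlier scan period may contribute and cannot be told apart: the slope was 0.89, between the bounds of 0.8 and 0.95, and the share of differences against the p38WT effect decides nothing, as they contain it with a minus sign. Over all genes the p38DN fold changes were not smaller (total least squares slope 1.142, SD 0.938 against 0.875), but these values include the spread between arrays, among them the liver transcripts. Genotype cannot be told apart from batch, because 0 slides held both genotypes.

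Other groupings of the same arrays were counted for each result, 100 per comparison with the real one included. Chance can be excluded for the genes changed by irradiation in p38WT (1 of 100 as large, 5088 genes, highest other 1778), p38DKI (1 of 100, 5893, highest other 1991) and p38DN (1 of 100, 5226, highest other 1404). It can be excluded for the difference of irradiation effects between p38DN and p38WT (1 of 100, 316, highest other 0). For p38DKI and p38WT 2 of 100 groupings gave as many genes (1, highest other 1), and a single gene, lost when any 1 of 15 arrays was left out, is too little to exclude chance. For p38DN and p38DKI it could not be excluded (5 of 100, 172 genes, highest other 699), and a grouping that calls 699 genes, several times the real count, points to a structure of the samples. Chance can be excluded for the differences before irradiation of p38DKI (1 of 100, 19, highest other 5) and p38DN (1 of 100, 10177, highest other 5958) from p38WT, and for p38DN after it (1 of 100, 8058, highest other 4647). After irradiation 1 of 100 groupings gave as many genes for p38DKI (815, highest other 699), but this is too close to call chance excluded: the count was 251 without p38DKI irradiated 2 and 426, 492, 535 and 315 without p38WT irradiated 1, 2, 3 and 4, all under 699, and 1 in a fit on only these groups. The grouping with 699 genes points to a structure of the samples there too. For the number of lists called it could not be excluded in p38WT (20 of 100, 15 lists, highest other 20), p38DKI (5 of 100, 17, highest other 18) or p38DN (5 of 100, 14, highest other 16). The median of the other groupings was 11, 11 and 9 lists, so list calls at the preset correlation were frequent in them. Each of these groupings left the doses unequal, so part of the dose effect stayed in it. They therefore cannot show how often lists are called without any effect.

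Among 300 groups of 5 values tested, 35 had an array far from the other 4, where chance gives about 1 in 20 such groups. On p38WT unirradiated array 4 the scores of p53 targets (-0.54, others -0.41 to -0.38), interferon-stimulated genes (-0.62, others -0.2 to -0.11) and NRF2 genes (-0.51, others -0.17 to -0.07) and the level of Ifit3b (-2.25, others -0.41 to 0.04) were low. On p38WT unirradiated array 5 the cell cycle score was 0.02 (others 0.37 to 0.46) and the level of Cdkn1a -0.12 (others -2.09 to -1.72). On p38WT irradiated array 3 the median CV of repeated spots was 22.22% (others 5.2 to 6.19), the apoptosis score -0.05 (others 0.5 to 0.66), the glucocorticoid score 0.85 (others 0.41 to 0.52) and H2-Eb2 -3.8 (others -5.75 to -5.3). Slfn3 stood at 1.7 on p38WT irradiated array 1 (others 1.15 to 1.25). The heart marker level was 2.49 on p38WT irradiated array 2 (others -2.7 to -2.01) and 1.65 on p38DN irradiated array 3 (others -2.29 to -1.85), where Marco stood at 4.69 (others 6.29 to 6.63). On p38DKI unirradiated array 1 the DNA repair score was 0.29 (others 0.48 to 0.55) and Cxadr -1.47 (others -4.71 to -4.02). The liver marker excess on that array was 4.28. The p53 target score was -0.91 on p38DN unirradiated array 3 (others -0.78 to -0.75) and the glucocorticoid score -0.45 on p38DN unirradiated array 1 (others -0.89 to -0.8).

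On p38DKI irradiated array 2, the array with the most liver transcripts, many blood cell scores were low. The B cell score was -3.62 (others -1.72 to -1.2), T cell -2.3 (others -0.39 to 0.03), NK cell -1.17 (others 0.97 to 1.37), dendritic cell -1.63 (others -0.12 to 0.04) and eosinophil, basophil and mast cell -1.09 (others 0.07 to 0.44). The p53 target score was 0.24 (others 0.61 to 0.7), cell cycle -1.62 (others -0.31 to 0.05), interferon-stimulated -0.12 (others 0.87 to 1.12), p38 pathway -0.75 (others 0.01 to 0.11) and inflammatory -0.76 (others 0.32 to 0.54). Immediate early genes scored -0.99 (others 0.05 to 0.35), apoptosis regulators -0.34 (others 0.5 to 0.63) and ribosomal protein genes -0.88 (others -0.05 to 0.28). Ifit3b stood at 3.13 (others 4.34 to 4.64), Fcmr at -2.51 (others 0.16 to 0.76), Srpk3 at -5.6 (others -3.67 to -3.45) and Chst3 at -4.43 (others -2.85 to -2.54).

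Differences between genotypes in the irradiation effect are given here as log2 values without correction for the median of all genes. For p38DKI minus p38WT 1 gene passed, Olfr1402 (-2.01), and the lists called were monocyte (0.357) and erythroid markers (-0.982). For p38DN minus p38WT 316 genes passed, and the lists were B cell (1.334), NK cell (-0.802), neutrophil (-1.144), monocyte (0.891), dendritic cell (0.613) and erythroid markers (-0.61), cell cycle (0.37), DNA repair (0.468), MHC class II (1.481) and heme synthesis genes (-0.586). Its named genes were Mcpt8 (3.567) and Cyp11a1 (2.879), both at background in p38DN, Clec10a (3.498), Rtn1 (3.383), Ddr1 (3.091), H2-Q10 (-4.281), Acot1 (-3.52), Csta2 (-3.412), S100a2 (-3.412) and Steap4 (-3.108). For p38DN minus p38DKI 172 genes passed, and the lists were B cell (1.494), T cell (0.919), neutrophil (-0.701), eosinophil, basophil and mast cell (0.888) and platelet markers (0.981), cell cycle (0.863), MHC class II (1.171), NRF2 (-0.125), ribosomal protein (0.439), heme synthesis (-0.089) and RNA quality genes (-0.149). Its named genes were Mcpt8 (4.062), Crisp3 (3.152) and Klk1b27 (2.856), all at background in p38DN, Cd8b1 (3.36), Sptb (2.883), Stbd1 (-5.4), Il1rap (-5.334), H2-Q10 (-4.209), Klhl13 (-3.551) and Rmdn2 (-3.512). With an estimated correlation none of these lists kept its call (adjusted p of 0.623 or more).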

How the results depend on the processing

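Counts depended on the setting, and the cause was not tested. In p38WT and p38DKI slide is partly bound to dose. A fit of their irradiation effects with slide as a fixed block rests on 1 unirradiated p38WT array and 1 irradiated p38DKI array. The blocked difference between p38DKI and p38WT rests on that p38WT array before irradiation and on that p38DKI array after it. Most called lists depended on the preset correlation: 46 of the calls over the irradiation effects fell to 6 with an estimated correlation, and fry gave 42. The numbers of the mice did not pair the arrays in p38WT and p38DKI, where correlations between same-numbered arrays ranged from -0.124 to 0.303 and from -0.216 to 0.397. In p38DN (-0.149 to 0.411, over 0.1 in 3 of 5 pairs, own number best in 3) the same number meant the same slide and scan day, and the fit with slide as a fixed block, which takes the differences within these pairs, gave 4981 genes. With the replicate number as a block the difference p38DKI minus p38WT had 0 genes, and no other count moved by over 1.5 times. The p38DN unirradiated arrays 4 and 5 were closer than any other pair of a group (SD of differences 0.205, next 0.293, median 0.514), so they were also counted as 1 array. That alternative, the 75th percentile over probes detected on all arrays, the omission of the 4 arrays highest in liver transcripts and the liver covariate were added after the data had been seen. Comparisons below are called the effect (irradiation), the difference of effects, the difference before and the difference after irradiation.

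At an adjusted p under 0.01 the effects had 3090 (p38WT), 3333 (p38DKI) and 3192 (p38DN) genes, the differences of effects 0 (p38DKI minus p38WT), 8 (p38DN minus p38WT) and 22 (p38DN minus p38DKI), and p38DKI minus p38WT 8 before and 95 after irradiation. With at least a 2-fold change the effects had 2877, 3324 and 3223 genes, and after irradiation p38DKI minus p38WT had 441 and p38DN minus p38WT 5289. At an unadjusted p under 0.001 the effects had 2770, 2848 and 2828, the differences of effects 130 for p38DKI minus p38WT and 289 for p38DN minus p38DKI, the differences before 87 (p38DKI) and 6365 (p38DN) and those after 519 and 4856.

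Normexp background correction adds an offset that shrinks log2 changes of dim probes. Lost calls and smaller medians under it may stem in part from that. The smallest liver marker excess on the 4 liver-high arrays, for example, was 3.73 with it and 7.8 in the main scaling. With this correction the effects had 1326, 1381 and 445 genes, the differences of effects 0, 1 and 1, p38DKI minus p38WT 1 before and 1 after, and p38DN minus p38WT 934 after. The correlation with p38WT was 0.354 for p38DKI and 0.2 for p38DN. Directions turned for ribosomal protein genes in p38DN (0.155), for erythroid markers in p38DKI minus p38WT (test direction, median -0.064) and p38DN minus p38WT (0.276) and for heme synthesis genes there (0.158). They also turned for ribosomal protein genes before irradiation (-0.331) and for platelet markers (0.211) and p38 pathway genes (0.095) after it, p38DKI minus p38WT. Genes that turned were Cd200r3 (0.107) and Prkdc (0.021) in p38WT, and Rtn1 (-0.019), Cyp11a1 (-0.22), Cd200r3 (-0.191) and Tnfrsf10b (-0.477) in p38DN minus p38WT.

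Array median scaling gave 0 genes (p38DKI minus p38WT), 1.1e+02 (p38DN minus p38WT, 63 higher and 48 lower) and 39 (p38DN minus p38DKI) for the differences of effects, and 12 before and 165 after for p38DKI minus p38WT. Quantile normalization gave 0, 538 and 370 for the differences of effects. No scaling gave 3375 for the effect in p38DN, 4 and 22 for the differences of effects of p38DKI from p38WT and of p38DN from p38DKI, and 7 before and 76 after for p38DKI. Deposited values gave 76 for p38DN minus p38DKI, 8 before and 321 after for p38DKI minus p38WT, and turned Pes1 (0.217) and, for p38DN before irradiation, Neurog3 (0.103). Without the filter on dim probes the differences of effects had 0, 81 and 52 genes, p38DKI minus p38WT 336 after, and the correlation of p38WT and p38DKI was 0.612. Probes well above background on all arrays gave 5 for the difference of effects and 6 before and 1320 after for p38DKI minus p38WT, 6016 before and 5112 after for p38DN, and a correlation of 0.692 for p38WT and p38DN.

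A trended and robust variance gave 0 for the difference of effects of p38DKI from p38WT, as did the scan date as a block. Array weights gave 74, 2742 and 3600 for the differences of effects, and 1025 before and 413 after for p38DKI. Slide as a random block gave 75, 479 and 259, and 35 before and 1912 after. Slide as a fixed block gave 165 and 679 for the effects in p38WT and p38DKI, 2 and 0 for the differences of effects of p38DN from p38WT and from p38DKI, 2 before and 1 after for p38DKI, a correlation of 0.418 for p38WT and p38DN, and turned platelet markers in p38DN minus p38DKI (-0.037). Slide as a fixed block and scan date as a block gave no value for p38DN against p38WT within a dose. Fits on only the groups of a comparison gave 0, 526 and 26 for the differences of effects and 1 after for p38DKI.

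Of the alternatives added later, the 75th percentile over probes detected on all arrays gave 0 for the difference of effects and 30 before for p38DKI minus p38WT. Omitting the 4 liver-high arrays gave 0, 705 and 38 for the differences of effects, 33 before and 339 after for p38DKI, a correlation of 0.774 for p38DKI and p38DN, and turned the tests of T cell markers (0.047), ribosomal protein genes (0.001) and RNA quality genes (0.145) in p38DN minus p38DKI. Counting p38DN unirradiated 4 and 5 as 1 array gave 0, 136 and 47. The liver covariate gave 4, 1004 and 41, 261 before and 1.1e+02 after (40 higher and 74 lower) for p38DKI, and turned T cell markers in p38DN minus p38DKI (-0.057), NK cell markers before irradiation in p38DKI (0.079) and the test of T cell markers before irradiation in p38DN (-0.09).

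With each array left out in turn the differences of effects ranged from 0 to 59 (p38DKI minus p38WT), 92 to 444 (p38DN minus p38WT) and 49 to 682 (p38DN minus p38DKI), and p38DKI minus p38WT from 9 to 31 before and 251 to 1049 after irradiation. All other alternatives left the counts within 1.5 times.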

Other observations

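The list of eosinophil, basophil and mast cell markers was not called by irradiation in p38WT (adjusted p = 0.345) or p38DKI (adjusted p = 0.117), and its members moved apart. The basophil gene Mcpt8 fell at least 5.61-fold in p38WT and at least 6.96-fold in p38DKI, and Cd200r3 at least 2.34-fold and 2.71-fold. In p38DN both genes were above background on 0 of 5 arrays at either dose, so a change could not be measured there. Hdc, the histidine decarboxylase gene, rose 5.99-fold in p38WT, 4.41-fold in p38DKI and 5.89-fold in p38DN. Of 24 monocyte markers 4 rose and 3 fell in p38WT, 6 rose and 4 fell in p38DKI, and 10 rose and 2 fell in p38DN. Of single markers, Fcgr4 rose 3.71-fold, 2.26-fold and 3.25-fold in p38WT, p38DKI and p38DN, and Cx3cr1 fell 4.86-fold, 4.88-fold and 9.38-fold. Dendritic cell genes Flt3 and Irf8 fell 4.40-fold and 3.74-fold in p38DKI, and 3.75-fold and 5.09-fold in p38DN. Their list was called in neither with camera (adjusted p = 0.117 and 0.837). Of its 15 members 2 rose and 5 fell in p38DKI, and 3 rose and 3 fell in p38DN. The red cell enzyme gene Car1 fell 3.41-fold in p38WT, and Slc4a1 13.8-fold in p38DKI.

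The list of p38 pathway genes was not called by irradiation with camera (adjusted p = 0.198 in p38WT, 0.557 in p38DKI and 0.166 in p38DN). In p38WT 28 of its 40 measured members did not pass, but the genes of the p38 kinases themselves did. Mapk13 rose 3.8-fold (SE 0.309, adjusted p = 5.06e-05), Mapk12 fell 3.51-fold (SE 0.308, adjusted p = 9.65e-05), Mapk11 fell 3.01-fold (SE 0.275, adjusted p = 0.000113) and Mapk14 rose 1.85-fold (SE 0.227, adjusted p = 0.00426). In p38DKI Mapk13 (log2 0.75, SE 0.309, adjusted p = 0.0644) and Mapk12 (log2 -0.59, SE 0.308, adjusted p = 0.136) were not called. Mapk11 fell 2.58-fold there, and Mapk14 rose 1.73-fold (SE 0.227, adjusted p = 0.0094) on 1 of its 2 probes. None of these genes passed in the difference of irradiation effects between p38DKI and p38WT. In p38DN Mapk14 rose 2.42-fold. Oxidative stress genes moved apart: Txn1 rose 2.63-fold and 2.49-fold in p38WT and p38DKI, while Gpx1 fell 3.55-fold in p38DKI and 4.18-fold in p38DN, and Sod2 fell 2.89-fold in p38WT and 4.11-fold in p38DN.

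For the liver transcripts, Alb stood at 10.23, 9.19, 10.2 and 10.21 on p38DKI irradiated 2 and p38DN unirradiated 2, 4 and 5. The p38DN unirradiated arrays 4 and 5 were both rich in liver transcripts and the closest pair of a group. Mean heart marker levels were raised on p38WT unirradiated arrays 1 and 3 by 3.18 and 2.01, and the blood was drawn by cardiac puncture per the labels. Array p38WT irradiated 3 had 579 spots marked as outliers and 205 marked as non-uniform, and 39.72% of its probes were well above background.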
